A study of Mus musculus with 6 samples.

How the data were processed

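RNA was taken with Trizol from flash-frozen whole kidneys of mice at postnatal day 3, and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit, per the labels' protocols. There were 3 samples of wild type and 3 of R26NICD2/+ Kspcre. Groups and replicate numbers came from the sample labels. The labels do not say that the 3 samples of a group came from separate animals, and p-values then measure the spread between these samples, which may be technical in part. Replicate 3 of R26NICD2/+ Kspcre held no Y-linked transcripts, which the other libraries had, so not all samples of that genotype came from the same animal. For the remaining samples this cannot be told.

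The deposited data are 1 table with a row per gene. Its FPKM (fragments scaled to transcript length and to mapped fragments) were computed by the authors and given to 2 decimals for each sample, per the file headers. The authors' table also holds mean FPKM per group and, per the file headers, a log2 fold change, p-value and q-value from the authors' DEGseq comparison of the groups, and the length of each gene's longest transcript, another deposited value. The submitters' processing notes name Bowtie 0.12.2 and the build mm8, while the chromosome accessions and gene positions in the table are those of GRCm38, so coordinates are given on GRCm38 as the table has them. The program that made the FPKM, the treatment of strand and the treatment of reads shared by gene copies are not given in the sources used here. No separate batch is labelled. Of 23669 rows, 4010 held no FPKM in any library and were left out, and 1676 rows were genes the authors' annotation did not name. The single symbol on more than 1 row was represented by the row of highest mean. A set of 27 columns comparing pairs of samples was not used.

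Depth was not stated and was estimated. For short genes of low level, FPKM values fall on whole multiples of the value of 1 fragment, and the library size that made most values whole was taken. It came to 16050000 to 17000000 fragments, with 86.5% to 90.1% of the low values within 0.15 fragments of a whole number, where 30.0% are by chance. Depth differed little between libraries, so genes near 1 FPKM have the least precise values in all 6.

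Since the table holds FPKM and not counts, the branch of the design for normalized values was used. Values were transformed to log2(FPKM + 1), genes with at least 1 FPKM in at least 3 libraries were kept (13765 genes), and NICD2 was compared with wild type in all 6 libraries with limma 3.58.1 (R 4.3.3), with a mean-variance trend, no robust option and no other covariate. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and the test is two-sided. The test was run on simulated FPKM with the levels and spread of the 13603 genes kept there, a set of them changed. It recovered 57.4%, 92.4% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale in this comparison, and 5.14% of its calls were false. The changed genes were drawn only from those above a minimum wild type level, so recovery near 1 FPKM was not simulated. The spread was drawn independently for each gene.

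Before the data were examined, 44 gene lists of nephron segments, other cell types and pathways, the alternatives and the rule for named genes were fixed. Of these lists 43 had at least 5 tested members and were tested with camera (limma, inter-gene correlation preset to 0.01), adjusted over the 43. The list of sex-linked genes served as a check of the libraries. Besides the count over all genes tested, each list's count adjusted over the list alone is given. The camera test was repeated with the correlation estimated per list, and with fry, which tests whether a list's genes move without comparing them with other genes. Genes that could be named were Notch2 and the members of both Notch lists, the 12 called genes with the highest and the 12 with the lowest fold change among those with groups that did not overlap, a mean of at least 2 FPKM and an assigned symbol, and up to 4 members of each list with the smallest p. Any other gene is said to be chosen after its values were seen.

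Alternatives were a pseudocount of 0.1, no filter on low values, the replicate number as a block, and each library left out in turn. A stricter filter, median-ratio scaling, upper-quartile scaling and a term for the library without Y-linked transcripts were added after seeing the data, as were the tests of the pathway labels in the deposited table and of MHC class I genes. Alternatives that need counts (other count normalizations, a CPM filter and count models) could not be run. Pathway labels were tested with one-sided Fisher's exact tests over 320 KEGG pathways of 10 to 300 tested genes, among 7393 genes with a label, adjusted within each direction. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, those tests and figures.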

Results

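The series measured gene expression in whole kidneys of mice at postnatal day 3. It holds 3 wild type samples and 3 of the genotype R26NICD2/+ Kspcre, called NICD2 here. The allele carries the intracellular domain of Notch2 at the Rosa26 locus. This is the fragment that a Notch receptor releases on activation and that switches on target genes in the nucleus. Kspcre is a Cre recombinase under the promoter of Ksp-cadherin (Cdh16), which is active in kidney tubule epithelium. The title of the series gives the question as what active Notch2 signalling does to the kidney in cyst growth. The table has 23669 gene rows. The depth, estimated from the steps between low FPKM values, was 16050000 to 17000000 fragments per library, and 13568 to 13784 genes reached 1 FPKM in each. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.985 to 0.990 within groups and 0.968 to 0.980 between groups. NICD2 replicate 3 had 0 FPKM for the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, which were expressed in the other 5 libraries. Below, pairs of levels are mean FPKM of wild type and then NICD2, ± SD where given (n = 3 per group). Fold changes are of log2(FPKM + 1), NICD2 minus wild type, ± SE, a scale that understates changes of low genes. In whole kidneys a cell-type list can move with the share of its cells or with expression per cell, which FPKM cannot tell apart.

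The row that the table names for human Notch2 is taken here as the transgene, although the labels do not say that the allele holds human sequence. It held 0, 0.03 and 0.03 FPKM in the wild type libraries. In the NICD2 libraries it held 75.4, 79.6 and 60.2 FPKM (limma log2 fold change 6.15 ± 0.11, adjusted p = 3.32e-08). Mouse Notch2 (gene 18129, chromosome 3, 98013538 to 98150367 on GRCm38) was at 17 ± 1.48 and 17.3 ± 0.835 FPKM (log2 fold change 0.02 ± 0.08, adjusted p = 0.894). Of known Notch targets, Nrarp, a feedback inhibitor of Notch signalling, was at 18.6 ± 1.73 and 145 ± 25.4 FPKM (log2 fold change 2.88 ± 0.12, adjusted p = 6.40e-06). The transcriptional repressors Heyl and Hey2 were at 18.5 ± 0.71 and 72.9 ± 12.7 FPKM and at 3.96 ± 0.209 and 9.04 ± 0.425 FPKM (adjusted p = 4.25e-05 and 1.26e-04). Hes1, another repressor, was at 34.5 ± 3.7 and 58.2 ± 2.89 FPKM (adjusted p = 0.00114). The related Hey1 was not called, at 13.5 ± 1.1 and 13.1 ± 0.459 FPKM (adjusted p = 0.779).

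Of the 15 tested members of the Notch target list, 10 rose and none fell, with a median log2 fold change of 0.60. The Notch target list had 11 genes higher and 0 lower adjusted over the list alone. Camera gave the Notch target list adjusted p = 3.06e-10, and adjusted p = 0.176 with an estimated correlation. Ccnd1, which encodes the cell cycle regulator cyclin D1, was at 95 ± 0.806 and 221 ± 14.4 FPKM (adjusted p = 2.17e-05). Dtx1, Notch3, Bcl2, Myc and Id4 also rose, while Hey1, Dtx3, Dtx4, Gucy1a3 and Sox9 were not called. Id4 lost its call in 4 of the 6 fits that left out a library, with adjusted p up to 0.105.

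Among 24 tested receptors, ligands and cofactors of the pathway, 3 rose and 2 fell. The ligand Jag1 was at 24 ± 2.37 and 48 ± 1.47 FPKM (adjusted p = 1.69e-04). The receptors Notch3 and Notch1 rose too, at 15.6 ± 1.02 and 26.6 ± 1.74 FPKM and at 16.3 ± 0.677 and 25.7 ± 2.81 FPKM. The ligands Dll1 and Jag2 fell, at 11.8 ± 0.796 and 7.88 ± 1.04 FPKM and at 5.26 ± 0.491 and 3.57 ± 0.383 FPKM (adjusted p = 0.013 and 0.0251). Dll1 lost its call without wild type replicate 3 (adjusted p = 0.0529), and Jag2 in 4 of the 6 fits, with adjusted p up to 0.104. The list of Notch receptors and ligands had 4 genes higher and 3 lower adjusted over the list alone. Camera gave the list of Notch receptors and ligands adjusted p = 0.843, and adjusted p = 0.948 with an estimated correlation. In the list of Notch receptors and ligands limma called 1 gene lower without wild type replicate 1, 2 or 3, or NICD2 replicate 1 or 3, or with no filter on low values. Its median was -0.03 and its mean 0.01.

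**Figure D1:**
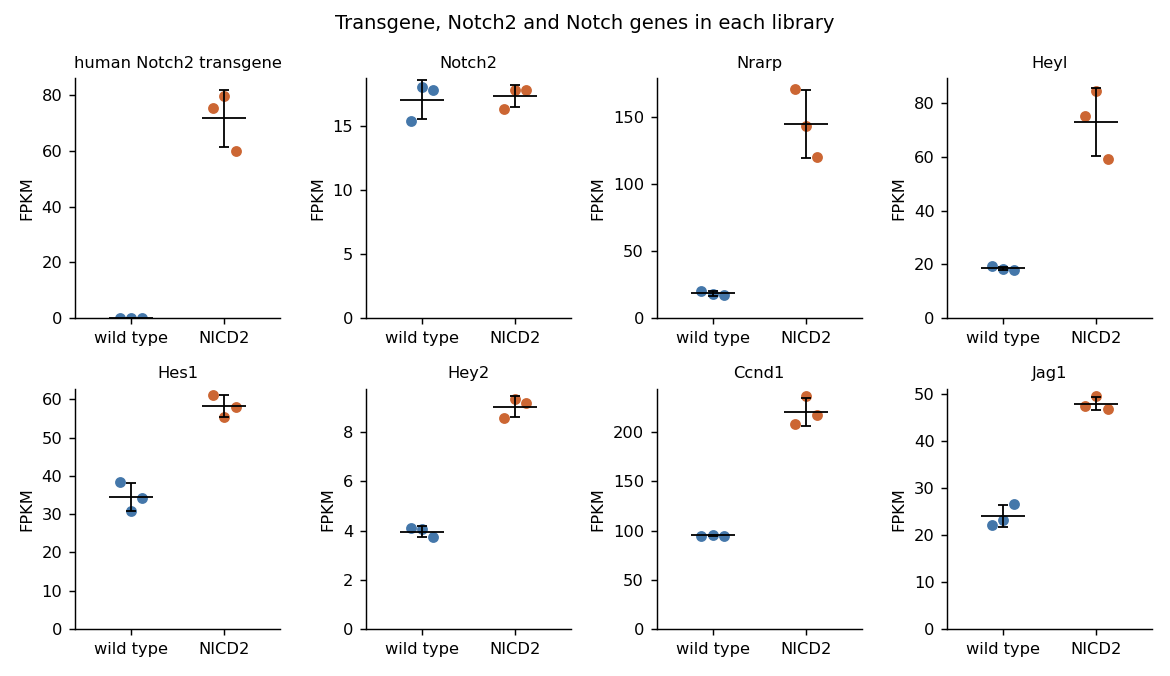
FPKM of the transgene, mouse Notch2 and 6 Notch genes in each of the 3 wild type (blue) and 3 NICD2 (orange) libraries, with black bars for the mean ± SD. The transgene was at 60.2 to 79.6 FPKM in NICD2 and at most 0.03 FPKM in wild type, while mouse Notch2 overlapped between groups.

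Across 13765 genes tested with limma, 1210 were called at an adjusted p under 0.05, of which 679 were higher and 531 lower in NICD2. An unadjusted p under 0.05 was reached by 3450. A log2 fold change of at least 1 in size was reached by 147 of the higher and 51 of the lower genes, and the median size over called genes was 0.50. Apart from the transgene, the largest rise was in Rhov, at 0.857 ± 0.274 and 31.5 ± 5.77 FPKM (log2 fold change 4.12 ± 0.15, adjusted p = 4.15e-06). Fgfbp1, a carrier of fibroblast growth factors, was at 4.07 ± 0.277 and 63 ± 15.8 FPKM (log2 fold change 3.63 ± 0.15, adjusted p = 6.03e-06). The carboxylesterase Ces1d was at 0.76 and 19 FPKM, and Cbs, cystathionine beta-synthase, at 1.09 and 22.3 FPKM. Gc, the vitamin D binding protein, was at 3.07 and 39.6 FPKM, S100a14 at 3.87 and 37.5 FPKM, and Efna3 at 2.41 and 19.3 FPKM. Ivl, the squamous epithelial protein involucrin, was at 0.493 and 7.96 FPKM, and Sfn, the 14-3-3 sigma protein of stratified epithelia, at 13.8 and 72.8 FPKM. Hp, haptoglobin, was at 3.47 and 22.8 FPKM. Nrarp was also among the 12 highest. Scgb3a2, a secretoglobin, was listed at 0 in every wild type library and at 3.93, 11.2 and 5.19 FPKM in the NICD2 libraries (adjusted p = 5.72e-04).

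The largest fall was in Psca, prostate stem cell antigen, at 19 ± 8.2 and 0.187 ± 0.122 FPKM (log2 fold change -4.00 ± 0.25, adjusted p = 4.30e-05). Aqp6, an intracellular water channel, was at 12.2 ± 1.45 and 0.407 ± 0.155 FPKM (log2 fold change -3.24 ± 0.12, adjusted p = 4.15e-06). Sprr1a, a cornified envelope protein, was at 39.4 and 3.55 FPKM, the uroplakin Upk1b at 10.9 and 0.433 FPKM, and Tldc2 at 4.78 and 0.237 FPKM. The other 7 of the 12 lowest were Slc4a9, Slc26a4, Atp6v0d2, Atp6v1c2, Atp6v1g3, Foxi1 and Hepacam2, which belong to the intercalated-cell list. The groups did not overlap for any of the 1210 called genes, nor for 4198 of all 13765 tested, where chance gives 10%. The authors' deposited table, from a DEGseq comparison of the groups, gave a q under 0.05 to 9160 of 18724 genes, 4293 higher and 4867 lower. All 1210 genes called here were among them with the same sign. The same groups underlie both comparisons, and groups that do not overlap all but fix the sign, so this is no independent check. The count of called genes was 624 without wild type replicate 2, 780 without wild type replicate 3 and 729 without NICD2 replicate 1. Ces1d and Sprr1a share sequence with close gene copies, and how the authors divided shared reads is not given in the sources used here.

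**Figure D2:**
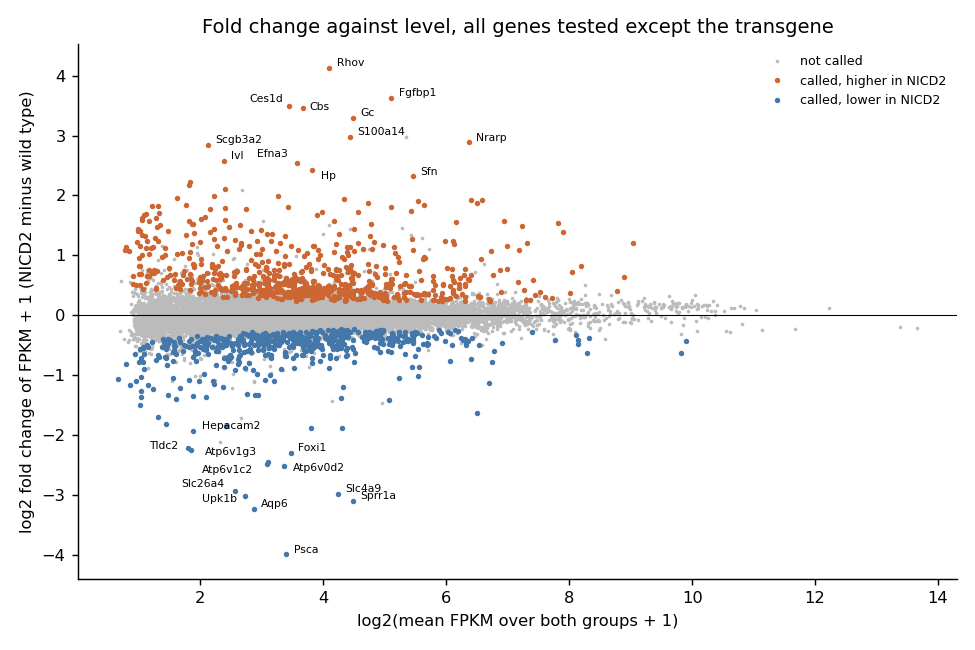
Log2 fold change (NICD2 minus wild type, of FPKM + 1) against log2 of the mean FPKM + 1 for all tested genes except the transgene, with called genes in orange (higher) and blue (lower) and the 12 highest and 12 lowest named. Rhov lies highest at 4.12 and Psca lowest at -4.00.

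Markers of intercalated cells, the acid- or bicarbonate-secreting cells of the collecting duct, had the lowest median fold change of the 43 lists tested, -1.40. Of 22 tested members, 18 fell and 1 rose. The intercalated-cell list had 1 gene higher and 19 lower adjusted over the list alone. Camera gave the intercalated-cell list adjusted p = 9.62e-24, and adjusted p = 0.0418 with an estimated correlation. In the intercalated-cell list limma called no genes higher without wild type replicate 2 or 3, or NICD2 replicate 1. Foxi1, the transcription factor that specifies these cells, was at 17.6 ± 0.979 and 2.78 ± 0.616 FPKM (log2 fold change -2.31 ± 0.12, adjusted p = 1.50e-05). The anion exchangers Slc4a9 and Slc26a4, the latter known as pendrin, were at 32.7 ± 0.527 and 3.27 ± 0.516 FPKM and at 9.52 ± 1.07 and 0.383 ± 0.262 FPKM (adjusted p = 2.24e-06 and 1.50e-05). The proton pump subunits Atp6v0d2, Atp6v1g3 and Atp6v1c2 were at 16.5 and 2.05 FPKM, at 13.6 and 1.66 FPKM and at 13.4 and 1.59 FPKM. Hepacam2 was at 4.83 and 0.527 FPKM. The member that rose was Rhbg, an ammonia transporter named after its values were seen, at 21.4 ± 2.25 and 29.5 ± 2.61 FPKM (adjusted p = 0.0203). The mean log2(FPKM + 1) of the list was 3.92 ± 0.005 in wild type and 2.45 ± 0.074 in NICD2 (SD).

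Principal cells, the salt- and water-handling cells of the same duct, had 5 of 16 tested markers lower and 3 higher, with a median of -0.27. The principal-cell list had 3 genes higher and 12 lower adjusted over the list alone. Camera gave the principal-cell list adjusted p = 8.14e-04, and adjusted p = 0.481 with an estimated correlation. The vasopressin-regulated water channel Aqp2 was at 135 ± 4.18 and 43.1 ± 7.46 FPKM (log2 fold change -1.64 ± 0.11, adjusted p = 5.81e-05). The water channels Aqp3 and Aqp4 were at 55.4 and 30.1 FPKM and at 8.74 and 2.9 FPKM. Hsd11b2, which inactivates glucocorticoids, was at 59.7 ± 2.69 and 32.2 ± 1.97 FPKM (adjusted p = 1.53e-04), and Fxyd4 at 49.9 and 23.4 FPKM. The 3 that rose were Krt18 at 77.8 and 175 FPKM, the sodium channel subunit Scnn1g at 22.4 and 39.5 FPKM and Elf5 at 9.31 and 14.4 FPKM. Cdh16, whose promoter drives the recombinase, was not called, at 274 ± 20.1 and 236 ± 19.6 FPKM (adjusted p = 0.164). Fxyd4, Scnn1g, Elf5 and Cdh16 were named after their values were seen, and Elf5 lost its call without wild type replicate 2 or 3 (adjusted p up to 0.073).

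**Figure D3:**
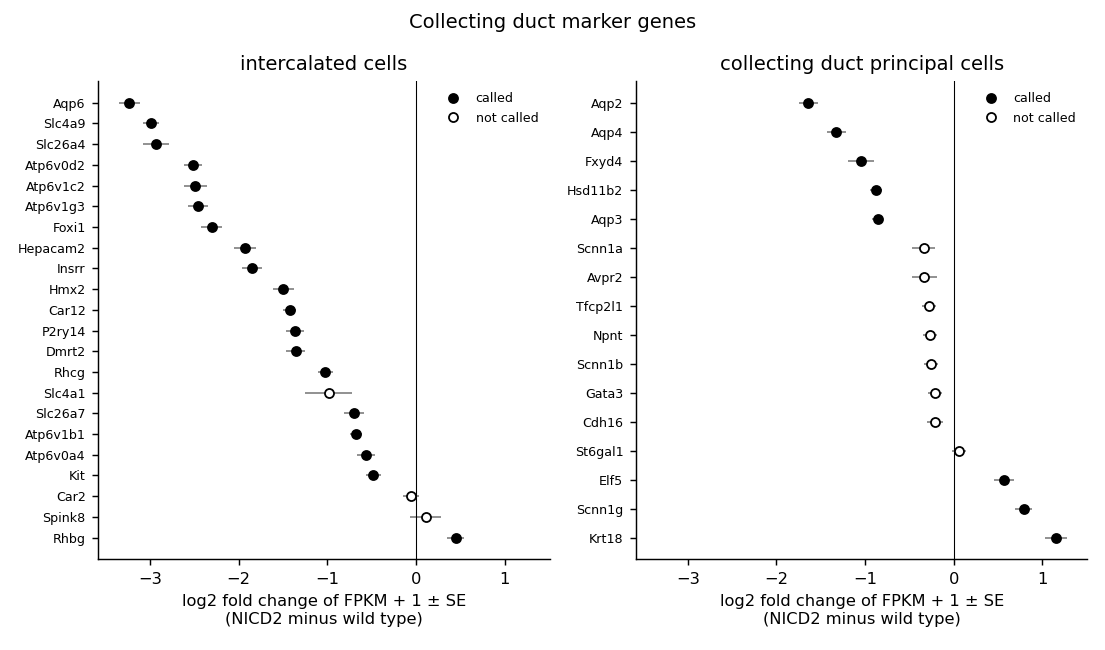
Log2 fold change (NICD2 minus wild type, of FPKM + 1) ± SE of each tested intercalated-cell marker (left, 22 genes) and principal-cell marker (right, 16 genes), with filled points for genes called. Intercalated-cell markers range from -3.24 (Aqp6) to 0.45 (Rhbg), and principal-cell markers from -1.64 (Aqp2) to 1.15 (Krt18).

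In the thin limb of the loop of Henle, 6 of 11 tested markers fell and 1 rose, with a median of -0.39. The thin limb list had 1 gene higher and 6 lower adjusted over the list alone. Camera gave the thin limb list adjusted p = 0.00233, and adjusted p = 0.327 with an estimated correlation. In the thin limb list limma called 3 genes lower without wild type replicate 2. The urea transporter gene Slc14a2 was at 30.1 ± 2.08 and 7.41 ± 0.478 FPKM (log2 fold change -1.89 ± 0.08, adjusted p = 5.72e-06). Aldose reductase (Akr1b3) was at 142 ± 6.84 and 64.2 ± 4.32 FPKM and the small heat shock protein Cryab at 106 and 62.6 FPKM. The tetraspanin Tspan8 rose, at 36.4 ± 1.16 and 88.4 ± 17.7 FPKM (adjusted p = 5.29e-04). In the thick ascending limb, 6 of 16 markers fell and 3 rose. The thick limb list had 4 genes higher and 7 lower adjusted over the list alone. Camera gave the thick limb list adjusted p = 0.0566, and adjusted p = 0.584 with an estimated correlation. In the thick limb list limma called 3 genes lower without wild type replicate 2. Without NICD2 replicate 2 or 3 the list was called lower (adjusted p = 0.0489 and 0.0228), as it was with no filter on low values (adjusted p = 0.0374). The Y-linked term, which in effect repeats the fit without NICD2 replicate 3, gave adjusted p = 0.0232. Umod, the urinary protein uromodulin, rose, at 114 ± 5.54 and 337 ± 33.6 FPKM (log2 fold change 1.55 ± 0.08, adjusted p = 2.20e-05). Egf fell, at 3.82 and 1.26 FPKM, as did Tmem207 at 1.15 and 0.03 FPKM and the chloride channel subunit Bsnd at 23.9 and 16 FPKM.

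In the distal convoluted and connecting tubule, 5 of 15 markers fell and 1 rose. The distal tubule list had 2 genes higher and 7 lower adjusted over the list alone. Camera gave the distal tubule list adjusted p = 0.00622, and adjusted p = 0.327 with an estimated correlation. In the distal tubule list limma called no genes higher without wild type replicate 1, 2 or 3, or NICD2 replicate 3, or with no filter on low values. Besides Hsd11b2, the calcium-binding protein Pvalb was at 1.66 and 0.24 FPKM, Emx1 at 19.9 and 13.6 FPKM and Klhl3 at 7.94 and 5.42 FPKM. The calcium channel Trpv5, named after its values were seen, was the member that rose, at 3.49 and 6.23 FPKM (adjusted p = 0.0293). In the proximal tubule, 6 of 29 markers fell and none rose. The proximal tubule list had 0 genes higher and 8 lower adjusted over the list alone. Camera gave the proximal tubule list adjusted p = 0.0213, and adjusted p = 0.621 with an estimated correlation. In the proximal tubule list limma called 3 genes lower without wild type replicate 2 or 3 or with no filter on low values. The phosphate transporter Slc34a1 was at 378 ± 13.3 and 245 ± 33.7 FPKM (adjusted p = 0.00579), Ttc36 at 131 and 86.8 FPKM and Kap at 1092 and 709 FPKM. The proximal list lost its call without wild type replicate 2 (adjusted p = 0.253) and without NICD2 replicate 2 (adjusted p = 0.114).

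In the glomerulus, 10 of 19 podocyte markers fell and none rose, with a median of -0.45. The podocyte list had 0 genes higher and 14 lower adjusted over the list alone. Camera gave the podocyte list adjusted p = 7.39e-09, and adjusted p = 0.327 with an estimated correlation. Wt1, a transcription factor of podocytes, was at 78.7 ± 6.28 and 55.4 ± 2.77 FPKM (adjusted p = 0.00473). The basement membrane collagens Col4a4 and Col4a3 were at 20.6 and 12.2 FPKM and at 16.9 and 9.31 FPKM. Of 11 nephron progenitor genes, Pax2 and Sall1 fell and none rose. The progenitor list had 0 genes higher and 5 lower adjusted over the list alone. Camera gave the progenitor list adjusted p = 0.0093, and adjusted p = 0.327 with an estimated correlation. In the progenitor list limma called 1 gene higher with no filter on low values, and 1 gene lower without wild type replicate 2, or NICD2 replicate 2 or 3. Pax2 was at 44.4 ± 3.84 and 32.4 ± 2.39 FPKM (adjusted p = 0.0125). Sall1 was at 28.3 ± 1.98 and 20.7 ± 2.15 FPKM (adjusted p = 0.0175) and lost its call in 4 of the 6 fits without a library, with adjusted p up to 0.0619.

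The renal vesicle list had 2 genes higher, Ccnd1 and Jag1, and 2 lower, Osr2 at 58.5 and 42.1 FPKM and Sfrp2 at 47.6 and 37.6 FPKM, of 15 tested. The renal vesicle genes had 2 genes higher and 3 lower adjusted over the list alone. Camera gave the renal vesicle genes adjusted p = 0.994, and adjusted p = 0.997 with an estimated correlation. Of the renal vesicle genes limma called 1 gene lower without wild type replicate 3, or NICD2 replicate 1 or 2. Their median was -0.09 and their mean 0.06. Sfrp2 lost its call in 3 of the 6 fits without a library, with adjusted p up to 0.0641. Of 11 ureteric tip and bud genes, Wnt7b, Ros1 and Wnt9b rose and Gfra1 fell. Wnt7b was at 11.2 ± 1.1 and 31.9 ± 2.13 FPKM (log2 fold change 1.43 ± 0.08, adjusted p = 3.63e-05), Ros1 at 1.74 and 4.29 FPKM and Wnt9b at 8.39 and 14.7 FPKM. The GDNF co-receptor Gfra1 was at 16.6 ± 1.21 and 9.68 ± 1.34 FPKM (adjusted p = 0.00361). The ureteric list had 5 genes higher and 3 lower adjusted over the list alone. Camera gave the ureteric list adjusted p = 0.408, and adjusted p = 0.728 with an estimated correlation. In the ureteric list limma called 2 genes lower without NICD2 replicate 1. Its median was -0.04, while its mean of 0.21 and its test pointed higher.

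Of 18 endothelial genes, 4 fell and none rose, with a median of -0.21. The endothelial list had 0 genes higher and 6 lower adjusted over the list alone. Camera gave the endothelial list adjusted p = 1.01e-05, and adjusted p = 0.481 with an estimated correlation. In the endothelial list limma called 1 gene lower without wild type replicate 2 or NICD2 replicate 1, or with no filter on low values, and 2 genes lower without wild type replicate 1 or 3, or NICD2 replicate 3. The sialomucin Emcn was at 93.1 ± 4.98 and 68.4 ± 2.66 FPKM (adjusted p = 0.00437). Tek, Egfl7 and Tie1 fell too, but lost their calls in 4, 5 and 5 of the 6 fits without a library, with adjusted p up to 0.153. Of 13 smooth muscle and pericyte genes, Notch3, Cnn1 and Tagln rose and none fell. The smooth muscle list had 5 genes higher and 0 lower adjusted over the list alone. Camera gave the smooth muscle list adjusted p = 0.00109, and adjusted p = 0.481 with an estimated correlation. In the smooth muscle list limma called 1 gene higher without wild type replicate 2 or 3, or NICD2 replicate 1 or 2, or with no filter on low values, and 5 genes higher without NICD2 replicate 3. Cnn1 and Tagln were at 9.45 ± 3.48 and 19.5 ± 3.27 FPKM and at 92.4 ± 18.3 and 160 ± 38.9 FPKM, and each lost its call in 4 of these 6 fits, with adjusted p up to 0.119. Among 16 stromal genes, Foxd1 fell, at 4.85 and 3.44 FPKM (adjusted p = 0.025), a call lost in 5 of the 6 fits. The stromal list had 0 genes higher and 4 lower adjusted over the list alone. Camera gave the stromal list adjusted p = 0.0341, and adjusted p = 0.621 with an estimated correlation. In the stromal list limma called no genes lower without wild type replicate 1 or 2, or NICD2 replicate 1 or 2, or with no filter on low values, and 2 genes lower with the stricter filter or upper-quartile scaling. It called 4 genes lower without NICD2 replicate 3. The list lost its call without wild type replicate 1, wild type replicate 2 or NICD2 replicate 1 (adjusted p = 0.113, 0.106 and 0.1765).

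Of 28 genes of DNA replication and S phase, 19 rose and none fell, with a median of 0.38. The S phase list had 24 genes higher and 0 lower adjusted over the list alone. Camera gave the S phase list adjusted p = 2.86e-15, and adjusted p = 0.351 with an estimated correlation. In the S phase list limma called 9 genes higher without wild type replicate 2, and 12 genes higher without NICD2 replicate 1. Gins2 and Mcm6, parts of the replicative helicase, were at 12.8 ± 1.01 and 21 ± 2.07 FPKM and at 42.5 ± 1.21 and 55.5 ± 2.1 FPKM (adjusted p = 0.00269 and 0.00588). The ribonucleotide reductase subunit Rrm2 was at 26.7 ± 1.49 and 39 ± 3.25 FPKM (adjusted p = 0.0043), and the primase subunit Prim1 at 16.2 and 22.3 FPKM. Of 28 genes of the G2 and M phases, Hmmr, Cdk1, Prc1 and Anln rose and none fell. The G2 and M list had 20 genes higher and 0 lower adjusted over the list alone. Camera gave the G2 and M list adjusted p = 6.10e-09, and adjusted p = 0.522 with an estimated correlation. In the G2 and M list limma called 1 gene higher without wild type replicate 2, or NICD2 replicate 1 or 2, or with no filter on low values. Hmmr was at 6.06 ± 0.853 and 9.14 ± 0.334 FPKM (adjusted p = 0.0126). Cdk1, Prc1 and Anln each lost their call in 4 of the 6 fits without a library, with adjusted p up to 0.165. Among 20 cyclins, CDK inhibitors and p53 targets, 4 rose and none fell. The cyclin list had 7 genes higher and 0 lower adjusted over the list alone. Camera gave the cyclin list adjusted p = 0.00348, and adjusted p = 0.351 with an estimated correlation. The 4 were Ccnd1 and Cdk6, which drive entry into the cycle, and Cdkn2b and Cdkn2a, which inhibit it. Cdk6 was at 7.82 and 18.7 FPKM, Cdkn2b at 0.923 ± 0.227 and 3.87 ± 0.183 FPKM and Cdkn2a at 0.103 ± 0.0896 and 1.34 ± 0.31 FPKM (adjusted p = 4.30e-05, 2.15e-04 and 0.00269).

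Of 21 genes of injured tubule and cyst epithelium, 10 rose and none fell, with a median of 0.56. The injury list had 14 genes higher and 2 lower adjusted over the list alone. Camera gave the injury list adjusted p = 7.37e-06, and adjusted p = 0.481 with an estimated correlation. In the injury list limma called 6 genes higher without wild type replicate 2 or 3, or NICD2 replicate 1 or 2, or with no filter on low values. The simple-epithelial keratins Krt8 and Krt18 were at 91.4 ± 5.31 and 197 ± 26.5 FPKM and at 77.8 ± 7.63 and 175 ± 31 FPKM (adjusted p = 3.86e-04 and 9.51e-04). Krt19 was at 21.1 ± 7.03 and 77 ± 17.9 FPKM (adjusted p = 0.00157), and osteopontin (Spp1) at 311 ± 13.3 and 734 ± 176 FPKM (adjusted p = 0.00166). In the matrix list, 6 of 27 genes rose and 1 fell. The matrix list had 8 genes higher and 2 lower adjusted over the list alone. Camera gave the matrix list adjusted p = 0.0566, and adjusted p = 0.714 with an estimated correlation. In the matrix list limma called 3 genes higher without NICD2 replicate 1, and no genes lower without wild type replicate 2 or 3, or NICD2 replicate 1 or 2. Fibronectin (Fn1) was at 115 ± 9.43 and 170 ± 18.7 FPKM (adjusted p = 0.00904), Tgfb2 at 6.54 and 10.9 FPKM and Ctgf at 26.9 and 41 FPKM. The proteoglycan Vcan, named after its values were seen, was the member that fell, at 28.2 and 22 FPKM (adjusted p = 0.0263). The matrix list was called higher without wild type replicate 2 or NICD2 replicate 1 (adjusted p = 0.0095 and 0.00235), and with no filter on low values (adjusted p = 0.0362).

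In the Wnt list, 4 of 26 genes rose and 2 fell. The Wnt list had 5 genes higher and 4 lower adjusted over the list alone. Camera gave the Wnt list adjusted p = 0.215, and adjusted p = 0.535 with an estimated correlation. In the Wnt list limma called no genes lower without wild type replicate 3, or NICD2 replicate 1 or 2, and 1 gene lower without wild type replicate 1 or 2 or with no filter on low values. Besides Wnt7b and Wnt9b, the feedback inhibitor Axin2 rose, at 6.08 ± 0.174 and 10.4 ± 1.27 FPKM (adjusted p = 0.00306), and so did Sp5, at 1.54 and 2.81 FPKM. Sfrp2 and the receptor gene Lgr5, at 3.62 and 2.51 FPKM, fell. Sp5 and Lgr5 were named after their values were seen and lost their calls in 5 and 6 of the 6 fits without a library, with adjusted p up to 0.114. Of 28 genes of growth factor, PI3K and mTOR signalling, 3 rose and 4 fell. The growth factor list had 4 genes higher and 5 lower adjusted over the list alone. Camera gave the growth factor list adjusted p = 0.816, and adjusted p = 0.948 with an estimated correlation. In the growth factor list limma called 2 genes lower without wild type replicate 2. Its median and mean were 0.02 and 0.01, while the direction of its test was lower. The fetal growth factor Igf2 was at 78.2 ± 11.1 and 220 ± 34.5 FPKM (log2 fold change 1.48 ± 0.13, adjusted p = 2.70e-04), and the EGF receptor ligand Tgfa at 4.54 ± 0.19 and 8.75 ± 0.464 FPKM (adjusted p = 3.60e-04). Egf fell, at 3.82 ± 0.746 and 1.26 ± 0.144 FPKM (adjusted p = 0.00146), as did the receptor Fgfr2, at 34.4 ± 0.932 and 25.8 ± 0.528 FPKM (adjusted p = 0.0037).

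Of 35 genes of inherited cystic kidney disease, Umod, Dzip1l and Pkhd1 rose and none fell. The cystic disease list had 3 genes higher and 0 lower adjusted over the list alone. Camera gave the cystic disease list adjusted p = 0.994, and adjusted p = 0.997 with an estimated correlation. Its median was -0.02 and its mean 0.04. Dzip1l was at 10.6 ± 0.55 and 16.1 ± 0.412 FPKM, and Pkhd1, mutated in recessive polycystic kidney disease, at 13.3 ± 0.742 and 19.1 ± 1.37 FPKM (adjusted p = 0.00132 and 0.00545). None of 30 genes of primary cilium assembly was called by limma, and 3 had an unadjusted p under 0.05. The cilium list had 0 genes higher and 0 lower adjusted over the list alone. Camera gave the cilium list adjusted p = 0.661, and adjusted p = 0.926 with an estimated correlation. None of 12 Hedgehog genes was called by limma, and 4 had an unadjusted p under 0.05. The Hedgehog list had 0 genes higher and 0 lower adjusted over the list alone. Camera gave the Hedgehog list adjusted p = 0.0142, and adjusted p = 0.351 with an estimated correlation. In the Hedgehog list limma called 1 gene lower without wild type replicate 3. Gas1 was at 29.6 and 24.3 FPKM. Of 19 cAMP genes, 1 rose and 3 fell. The cAMP list had 2 genes higher and 3 lower adjusted over the list alone. Camera gave the cAMP list adjusted p = 0.437, and adjusted p = 0.714 with an estimated correlation. The adenylyl cyclase Adcy6 was at 35.4 ± 1.36 and 25.1 ± 0.381 FPKM (adjusted p = 0.00171). The phosphodiesterases Pde1a and Pde4c fell too, at 9.21 and 5.48 FPKM and at 14.2 and 10.3 FPKM, and the receptor Ptger4 rose, at 3.09 and 5.57 FPKM.

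Interferon and immediate early genes were highest in NICD2 replicate 1. The mean log2(FPKM + 1) of interferon response genes was 3.81 there, 2.63 and 2.79 in the other NICD2 libraries and 2.54 to 2.66 in wild type. Of 18 tested interferon genes, Irf9 and Psmb8 rose, at 8.33 ± 0.304 and 19.8 ± 7.65 FPKM and at 6.17 ± 0.876 and 12.3 ± 4.3 FPKM (adjusted p = 0.0138 and 0.0321). Irf9 lost its call without wild type replicate 2 (adjusted p = 0.0602), and Psmb8 in 3 of the 6 fits without a library, with adjusted p up to 0.0993. The interferon list had 2 genes higher and 0 lower adjusted over the list alone. Camera gave the interferon list adjusted p = 0.00233, and adjusted p = 0.654 with an estimated correlation. In the interferon list limma called no genes higher without wild type replicate 2, and 1 gene higher without wild type replicate 1 or 3 or with no filter on low values. It called 1 gene lower without NICD2 replicate 1. Without NICD2 replicate 1 the interferon list lost its call (adjusted p = 0.08325). None of 17 immediate early genes, which respond within minutes to stimulation and handling, was called by limma, and 4 had an unadjusted p under 0.05. The immediate early list had 0 genes higher and 0 lower adjusted over the list alone. Camera gave the immediate early list adjusted p = 0.0126, and adjusted p = 0.682 with an estimated correlation. In the immediate early list limma called 1 gene higher without NICD2 replicate 3. The list lost its call without wild type replicate 3 (adjusted p = 0.154) or NICD2 replicate 1 (adjusted p = 0.1765). Its mean in replicates 1, 2 and 3 was 3.98, 3.5 and 3.15 in wild type and 4.87, 4.05 and 3.41 in NICD2, falling with the number in both groups. The groups overlapped, since wild type replicates 1 and 2 were above NICD2 replicate 3.

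Of 15 inflammation genes, Icam1 rose, at 8.14 ± 0.396 and 12.1 ± 2.4 FPKM (adjusted p = 0.0428), and lost its call in 5 of the 6 fits without a library, with adjusted p up to 0.113. The inflammation list had 7 genes higher and 0 lower adjusted over the list alone. Camera gave the inflammation list adjusted p = 0.00312, and adjusted p = 0.535 with an estimated correlation. In the inflammation list limma called no genes higher without wild type replicate 1, 2 or 3, or NICD2 replicate 1 or 2, or with no filter on low values, and 7 genes higher without NICD2 replicate 3. Of 16 macrophage genes, Cd14 and Itgam rose, at 1.38 ± 0.55 and 3.64 ± 1.25 FPKM and at 0.543 ± 0.126 and 1.22 ± 0.261 FPKM. Their calls were lost in 4 and 6 of the 6 fits, with adjusted p up to 0.159. The macrophage list had 3 genes higher and 0 lower adjusted over the list alone. Camera gave the macrophage list adjusted p = 8.15e-04, and adjusted p = 0.535 with an estimated correlation. In the macrophage list limma called no genes higher without wild type replicate 2 or 3, or NICD2 replicate 1 or 2, and 1 gene higher without wild type replicate 1 or NICD2 replicate 3, or with a pseudocount of 0.1 or no filter on low values. Its mean log2(FPKM + 1) was 3.61 in NICD2 replicate 1, 3.21 and 3.22 in the other NICD2 libraries and 2.88 to 3.2 in wild type. Of 5 tested lymphocyte genes, Cd8a rose, at 0.877 ± 0.176 and 4.41 ± 0.671 FPKM (adjusted p = 1.90e-04). The lymphocyte list had 1 gene higher and 1 lower adjusted over the list alone. Camera gave the lymphocyte list adjusted p = 0.645, and adjusted p = 0.926 with an estimated correlation. Of 5 neutrophil genes, Lcn2, which tubule cells also make, rose, at 6.01 ± 0.706 and 23.6 ± 10.2 FPKM (adjusted p = 0.0066). The neutrophil list had 1 gene higher and 0 lower adjusted over the list alone. Camera gave the neutrophil list adjusted p = 0.816, and adjusted p = 0.948 with an estimated correlation. Its median was -0.34 and its mean 0.06.

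Lists for tissues that a dissected kidney can carry differed between single libraries. The mean log2(FPKM + 1) of 14 adrenal genes was 1.05 in wild type replicate 3 and 0.722 in NICD2 replicate 1. In the other 4 libraries it was 3.87 to 3.99. No adrenal gene was called by limma, and 0 had an unadjusted p under 0.05. The adrenal list had 0 genes higher and 0 lower adjusted over the list alone. Camera gave the adrenal list adjusted p = 0.775, and adjusted p = 0.948 with an estimated correlation. Without wild type replicate 3 it was called lower (adjusted p = 0.0274). Of 8 erythroid genes, Kel rose, at 0.657 ± 0.153 and 2.74 ± 1.26 FPKM (adjusted p = 0.0186), a call lost in 3 of the 6 fits without a library. The erythroid list had 1 gene higher and 1 lower adjusted over the list alone. Camera gave the erythroid list adjusted p = 0.775, and adjusted p = 0.948 with an estimated correlation. In the erythroid list limma called no genes higher without wild type replicate 2 or 3, or NICD2 replicate 2, or with no filter on low values, and 1 gene lower without NICD2 replicate 1 or 3 or with the stricter filter. Hba-a1 was at 2647 FPKM in wild type replicate 1 and at 963 to 1546 FPKM in the other 5 libraries. None of 9 adipose genes was called by limma, and 5 had an unadjusted p under 0.05. The adipose list had 0 genes higher and 2 lower adjusted over the list alone. Camera gave the adipose list adjusted p = 0.00244, and adjusted p = 0.522 with an estimated correlation. In the adipose list limma called 1 gene lower without wild type replicate 2, and 2 genes lower without NICD2 replicate 3. Adipoq was at 7.69 ± 2.75 and 4.01 ± 1.29 FPKM.

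Of 7 markers of urothelium, the lining of the renal pelvis and ureter, 3 fell and 1 rose. The urothelial list had 2 genes higher and 5 lower adjusted over the list alone. Camera gave the urothelial list adjusted p = 0.0142, and adjusted p = 0.549 with an estimated correlation. In the urothelial list limma called no genes higher without wild type replicate 2 or 3 or with no filter on low values, and 2 genes higher without wild type replicate 1 or with the stricter filter. Psca and Upk1b were at 19 ± 8.2 and 0.187 ± 0.122 FPKM and at 10.9 ± 4.01 and 0.433 ± 0.344 FPKM. Upk3a was at 10.2 ± 5.53 and 3.15 ± 0.395 FPKM (adjusted p = 0.0209), while Upk1a rose, at 14.4 ± 5.03 and 37.7 ± 14.5 FPKM (adjusted p = 0.0211). Upk3a lost its call without NICD2 replicate 1 or 2, and Upk1a without wild type replicate 2 or 3, with adjusted p up to 0.0834.

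None of 29 genes of oxidative phosphorylation and the citrate cycle was called by limma, and 1 had an unadjusted p under 0.05. The respiration list had 0 genes higher and 0 lower adjusted over the list alone. Camera gave the respiration list adjusted p = 0.843, and adjusted p = 0.948 with an estimated correlation. Of 24 genes of fatty acid oxidation, Ppargc1a fell, at 14 ± 1.46 and 10.1 ± 0.687 FPKM (adjusted p = 0.0206), a call lost in 4 of the 6 fits without a library. The fatty acid list had 0 genes higher and 1 lower adjusted over the list alone. Camera gave the fatty acid list adjusted p = 0.44, and adjusted p = 0.93 with an estimated correlation. In the fatty acid list limma called 2 genes higher without NICD2 replicate 2, and no genes lower without wild type replicate 2 or 3, or NICD2 replicate 1 or 2. Without NICD2 replicate 2 the list was called higher (adjusted p = 0.0381). Of 20 glycolysis genes, Slc2a1, Pgk1 and Slc16a3 rose and Pfkm fell. Each lost its call in at least 4 of the 6 fits, with adjusted p up to 0.175. The glycolysis list had 6 genes higher and 2 lower adjusted over the list alone. Camera gave the glycolysis list adjusted p = 0.283, and adjusted p = 0.818 with an estimated correlation. In the glycolysis list limma called no genes higher without wild type replicate 3, or NICD2 replicate 1 or 2, and 1 gene higher without wild type replicate 2. It called no genes lower without wild type replicate 1, 2 or 3, or NICD2 replicate 1, 2 or 3, or with a pseudocount of 0.1, no filter on low values or median-ratio scaling. Of 17 hypoxia genes, Ddit4, Slc2a1 and Lox rose and none fell. Ddit4 was at 13.6 ± 1.65 and 29.8 ± 4.05 FPKM (log2 fold change 1.08 ± 0.11, adjusted p = 8.01e-04), and Lox lost its call in 5 of the 6 fits. The hypoxia list had 3 genes higher and 2 lower adjusted over the list alone. Camera gave the hypoxia list adjusted p = 0.0858, and adjusted p = 0.481 with an estimated correlation. In the hypoxia list limma called 1 gene higher without wild type replicate 3, or NICD2 replicate 1, 2 or 3. The list was called higher without NICD2 replicate 1 (adjusted p = 0.0315) and with no filter on low values (adjusted p = 0.0407).

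Of 22 apoptosis genes, 3 rose and 2 fell. The apoptosis list had 4 genes higher and 2 lower adjusted over the list alone. Camera gave the apoptosis list adjusted p = 0.125, and adjusted p = 0.535 with an estimated correlation. In the apoptosis list limma called 1 gene lower without wild type replicate 1 or 2, or NICD2 replicate 1 or 2. Mcl1 and Bcl2, which protect cells from death, were at 65.1 ± 2.33 and 97.9 ± 5.68 FPKM and at 8.64 ± 0.616 and 13.6 ± 0.0819 FPKM (adjusted p = 0.0011 and 0.0014). Pmaip1, which promotes it, was at 2.78 and 5.14 FPKM and lost its call without wild type replicate 2 (adjusted p = 0.0527). The caspase Casp6 was at 21.7 and 16.7 FPKM and Bcl2l11, named after its values were seen, at 8.72 and 6.67 FPKM. Bcl2l11 lost its call in 4 of the 6 fits without a library, with adjusted p up to 0.0846. Of 17 genes of the unfolded protein response, asparagine synthetase (Asns) and Herpud1 rose. The unfolded protein list had 2 genes higher and 0 lower adjusted over the list alone. Camera gave the unfolded protein list adjusted p = 0.0137, and adjusted p = 0.481 with an estimated correlation. In the unfolded protein list limma called 1 gene higher without wild type replicate 1, 2 or 3, or NICD2 replicate 1 or 2. Asns was at 4.81 ± 0.115 and 7.76 ± 0.357 FPKM (adjusted p = 0.00166). Herpud1 lost its call in 5 of the 6 fits without a library, and the list lost its call without NICD2 replicate 1 (adjusted p = 0.0533). Of 30 ribosomal protein genes, Rpl5 rose, at 153 ± 6.63 and 193 ± 9.15 FPKM (adjusted p = 0.0175), a call lost in 4 of the 6 fits. The ribosomal list had 1 gene higher and 0 lower adjusted over the list alone. Camera gave the ribosomal list adjusted p = 9.10e-06, and adjusted p = 0.565 with an estimated correlation. In the ribosomal list limma called no genes higher without wild type replicate 2 or 3, or NICD2 replicate 1 or 3, and 4 genes higher without wild type replicate 1.

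**Figure D4:**
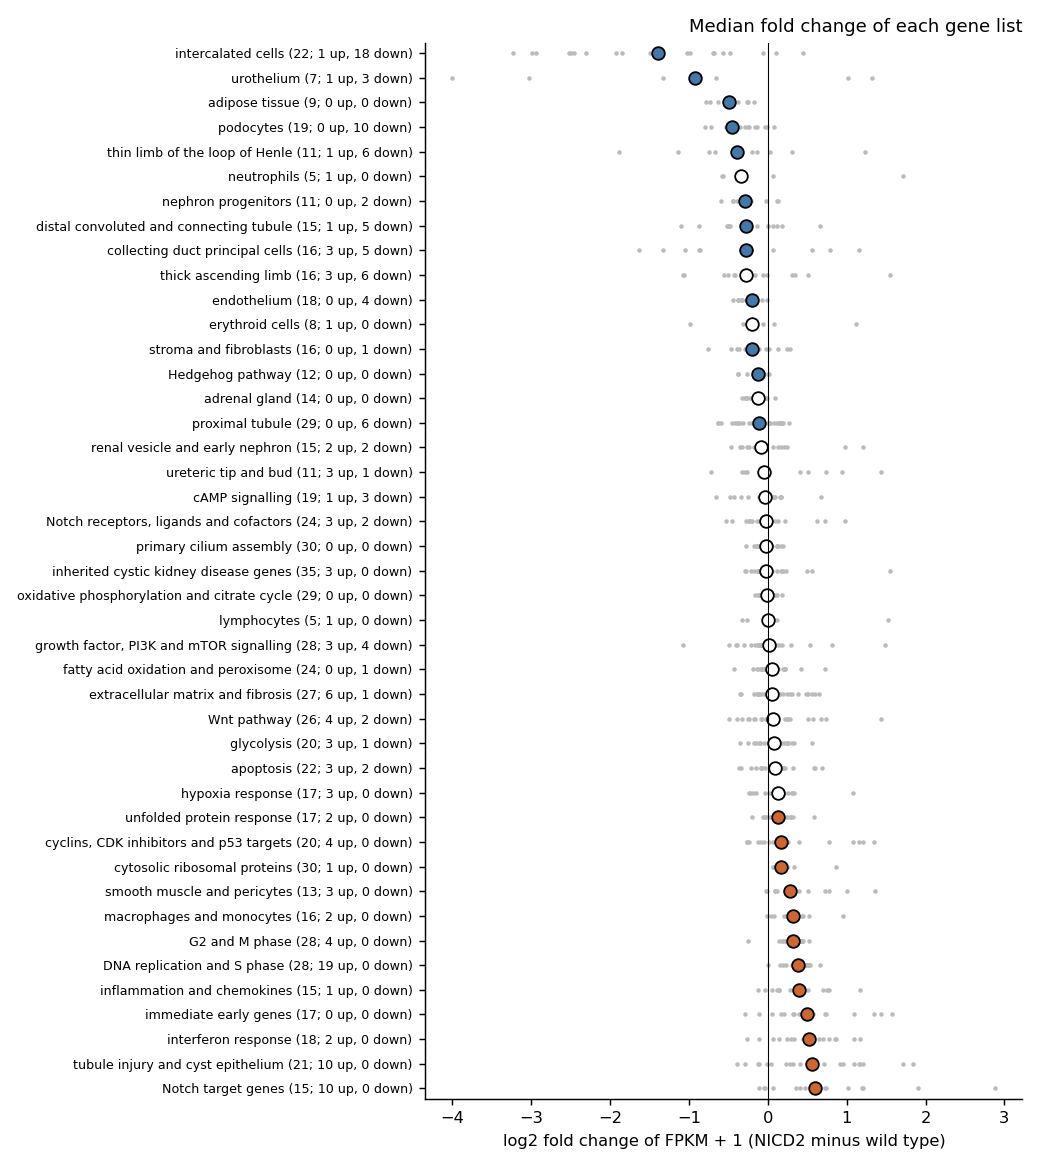
Median log2 fold change (NICD2 minus wild type, of FPKM + 1) of each of the 43 gene lists tested, as circles over grey points for the single members, with the number of members tested and called beside each name. Filled circles mark lists called higher (orange, 12) or lower (blue, 12) by camera with its preset correlation, of which the intercalated-cell list held with an estimated correlation.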

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

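The stricter filter, both scalings and the Y-linked term were chosen after seeing the data. The Y-linked term marks NICD2 replicate 3 alone, so it in effect leaves that library out and is no separate alternative. An effect of sex cannot be told apart from that library. The 1210 called genes (679 higher, 531 lower) ranged over 624 to 985 changed, 388 to 589 higher and 236 to 411 lower when 1 library was left out, with fewer samples in each fit. None of the 1210 genes changed sign under any of the 13 other settings. Since the groups did not overlap for any of them, leaving out a library or changing the pseudocount or filter could not change a sign. The kept signs are therefore no evidence of stability. Without wild type replicate 2 the split was 388 higher and 236 lower, without wild type replicate 3 it was 451 and 329, and without NICD2 replicate 1 it was 436 and 293. The other settings gave 894 (no filter) to 1346 (stricter filter) genes, 1192 with a pseudocount of 0.1, 1230 with median-ratio and 1262 with upper-quartile scaling, and 985 both with the Y-linked term and without NICD2 replicate 3, where 859 of the 1210 remained called. Of 127 named genes called, 33 lost their call in at least 1 of the 6 fits without a library. Mouse Notch2 was not called under any setting, and the transgene was called under every one.

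Over all tested genes, samples of the same number had correlations of deviations from the group means of -0.033, 0.059 and -0.045, and no sample correlated best with its own number in the other group. The highest values were 0.207 for wild type replicate 1 with NICD2 replicate 2, 0.235 for wild type replicate 2 with NICD2 replicate 3 and 0.246 for wild type replicate 3 with NICD2 replicate 1. The means of the immediate early and inflammation lists fell with the number in both groups, but the labels tie no numbers across groups. With the replicate number as a block 1055 genes were called (616 higher, 439 lower), 936 of them among the 1210, and 13 lists were called higher and 11 lower. Under the block the urothelial list lost its call (adjusted p = 0.0642) and the matrix list gained one (adjusted p = 0.0403). The block raised the genes called higher to 5 in the inflammation list, 5 in the macrophage list, 4 in the interferon list, 3 in the immediate early list and 2 in the urothelial list, and lowered those called lower in endothelium to 1. In the glycolysis list it left 1 gene called higher and none lower, and in the neutrophil and adipose lists 1 gene each was called lower.

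The list calls depend on the version of the list test. Of 12 lists called higher and 12 lower with the preset correlation, 0 and 1 were called with an estimated correlation, the 1 being intercalated cells. The distal tubule and progenitor lists lost their calls at estimated correlations of -0.021 and -0.051, below the preset 0.01. For these lists a larger correlation between genes is not what removed the call. Fry called 6 lists higher, 4 of them among the 12 and the others Wnt and hypoxia, and 7 lower, each among the 12. The Notch target list had adjusted p = 0.176 with an estimated correlation and 8.35e-04 by fry, and between 1.25e-11 and 1.86e-09 under the other settings. The Wnt list had an estimated correlation of 0.012, close to the preset, yet its unadjusted camera p went from 0.145 to 0.227. Both versions of camera therefore differ in more than the correlation. A call lost with an estimated correlation is thus not by itself a sign of correlated genes. How much each part adds to the spread was not tested. Alternatives that need counts were not run. Depth limits genes near 1 FPKM most. A change of 0.5 on the log2 scale was recovered in 57.4% of simulated genes, but these had no genes near 1 FPKM among those changed and no correlation between genes.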

Other observations

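All tests in this part were chosen after the results were seen, except that on genes near Rosa26. Genes of MHC class I antigen presentation, which shows peptides from inside the cell to T cells, rose in NICD2. Of 14 tested class I genes and partners, 9 rose and none fell, with a median log2 fold change of 1.02. Nlrc5, the transactivator of class I genes, was at 0.267 ± 0.0907 and 4.79 ± 1.01 FPKM (log2 fold change 2.18 ± 0.15, adjusted p = 6.14e-05), H2-K1 at 38.9 ± 4.86 and 151 ± 19.4 FPKM (adjusted p = 4.16e-05), H2-D1 at 19.4 ± 6.49 and 64.8 ± 5.99 FPKM, B2m, the shared light chain, at 210 ± 27.8 and 374 ± 48.4 FPKM (log2 fold change 0.83 ± 0.12, adjusted p = 0.00365) and the peptide transporter Tap1 at 5.7 ± 0.174 and 13.1 ± 6.26 FPKM (adjusted p = 0.0398). Tap1 lost its call without wild type replicate 1, 2 or 3, with adjusted p up to 0.124. H2-Q4, H2-Q7 and H2-Q8 also rose, and H2-Q9 was listed at 0 in every wild type library and at 1.64, 3.54 and 2.74 FPKM in NICD2, but these genes share sequence, so how reads divide among them is uncertain. None of 3 tested MHC class II genes was called by limma (median 0.13, and 0 had an unadjusted p under 0.05), with Cd74 at 22.3 ± 7.26 and 21.7 ± 3.16 FPKM.

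By the pathway labels in the authors' deposited table, 20 pathways were enriched among genes that rose and 6 among genes that fell, of 320 tested per direction. Antigen processing and presentation had 18 of 87 genes higher (adjusted p = 4.01e-05), which include 7 genes unnamed in the annotation whose labels are those of class I genes, cell cycle had 26 of 152 (adjusted p = 1.52e-05) and DNA replication 13 of 57 (adjusted p = 3.08e-04). Collecting duct acid secretion had 10 of 32 genes lower (adjusted p = 6.86e-05), among them Atp6v0d2, Atp6v1b1 and Atp6v1c2.

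More leukocytes in the NICD2 samples would raise leukocyte markers as much, but the mean change of the 14 tested class I genes and partners, called or not, was higher than that of 21 macrophage and lymphocyte markers by 0.70 ± 0.0748 (SE) on the log2 scale. The markers had a median of 0.28, so part of the rise may come from leukocytes. Cd8a rose by 1.52 ± 0.12 (SE), but the 5 tested lymphocyte genes had a median of 0.008, and limma did not call the other 4. Only these 5 of the 16 listed genes passed the filter, among them the B-cell genes Cd79a and Cd79b. Their median therefore says little about T cells. For the 7 called class I genes and partners within the MHC region on chromosome 17, another MHC haplotype in the NICD2 animals cannot be told apart from a change in transcription, because FPKM carry no alleles. B2m and Nlrc5 lie outside that region. A rise of class I transcription with the genotype stays open as a hypothesis, which reads that carry the alleles of these genes would test.

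The fall of intercalated-cell markers was weighed against less collecting duct in the NICD2 samples and against noise of weakly expressed genes. Less collecting duct would lower principal-cell markers as much. The mean of intercalated minus principal-cell markers changed by -1.15 ± 0.109 (SE) on the log2 scale. It was -1.45 to -1.38 in the wild type libraries and -2.77 to -2.43 in NICD2. So far as the principal-cell list follows the amount of duct, less duct is not the whole cause, though part of the fall may come from it. The list is an uncertain measure of duct, since 5 of its 16 markers fell and 3 rose. Its members Aqp2 and Aqp4 had log2 fold changes of -1.64 and -1.32, near the intercalated median of -1.40. Krt18 and Cdh16 are not particular to the duct. The fall was not confined to weakly expressed markers, which argues against noise at low levels as the whole cause. Of the 13 markers with a wild type mean of at least 10 FPKM, 10 fell and 1 rose, with a median log2 ratio of -1.48. These were picked by their wild type level, which in itself favours a fall, and belong to the same list. They are no separate evidence that the list fell. Fewer intercalated cells and lower expression per cell both stay open as hypotheses, untested here, which counts of cells stained for an intercalated-cell protein would separate.

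The urothelial list was lower in NICD2, which was weighed against one lower share of urothelium in those samples. Such a share would move every marker by 1 ratio. Here, unlike above, ratios were taken on log2(FPKM + 0.1). The log2 ratios of all 7 tested members ran from -6.06 (Psca) to 1.37 (Upk1a) and 1.42 (Krt5), 5 lower and 2 higher. Psca was at 0.08 to 0.32 FPKM in NICD2, so its ratio depends on the constant added and was -4.00 on log2(FPKM + 1). The SD that follows depends on it too. The SD between genes was 2.80 where the pooled SE of a ratio was 0.339 after removal of the library means. A lower share alone does not give that pattern, though part of the fall may come from it. A change of urothelial genes with the genotype stays open and was not tested.

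DNA of the strain in which the Rosa26 allele was made could change genes next to it, which was tested on genes within 10 Mb of Rosa26 (Gt(ROSA)26Sor, chromosome 6, 113067428 to 113077333 on GRCm38). Of 107 tested genes there 9 were called (8.41%), against 1201 of 13658 elsewhere (8.79%), an odds ratio of 0.953 with a 95% interval of 0.48 to 1.89 (Fisher's exact test, two-sided p = 1.0). No excess was detected, but the interval does not exclude odds up to 1.89 times those elsewhere.

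The 6 samples can be split into groups of 3 in 10 ways, too few for a share under 0.05. Each split other than the real one mixes the genotypes on both sides. A difference between the genotypes then adds to the spread within its sides and lowers its count of genes. The counts of the other splits therefore do not show what chance alone would give. The real split gave 1210 called genes and the highest other split 2, so that 1 of the 10 splits, the real one, reached that count. For the lists called by camera with its preset correlation the real split gave 24 and the highest other split 19, and 1 of the 10 splits, the real one, reached 24.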
